A study of Mus musculus with 6 samples.

How the data were processed

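The study compared 2 groups of 3 libraries each of mouse germinal centre B cells, sorted as Bach2-tdRFP low or high. Per the labels, each library held cells sorted from 3 mice and pooled, total RNA was extracted with Trizol, and libraries were made with a NEBNext Ultra kit for Illumina sequencing. Groups and replicate numbers were taken from the sample titles. The labels do not say whether low and high libraries with the same replicate number came from the same mice, and p-values measure the spread between these pooled samples.

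The authors deposited 1 table of FPKM per library (fragments scaled by transcript length and by the number of mapped fragments). TopHat2 2.0.8, Cufflinks 2.1.1 and the genome build mm9 are named per the submitters' processing notes, and the annotation is not given in the sources used here. Each deposited table held 23700 rows with the gene symbol, the position in mm9, the FPKM, its interval and a status. The deposited intervals were not used, since in the first table the FPKM lay outside its own interval in 10.36% of the rows above 0. Of 23234 symbols, 172 with a status other than OK in a library were left out, which included 4 with a failed estimate, and rows of the 250 symbols that stood on more than 1 row were summed. There were 6357 rows listed at 0 in every library. No row of an immunoglobulin constant region (0 rows) was present in the tables used here, so that list has no result. Kit and notes do not state whether reads were assigned by strand, so reads of overlapping antisense genes and of near-identical gene copies, such as globins, Bcl2a1 copies and ribosomal protein pseudogenes, cannot be told apart.

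FPKM are not counts, so no count test was used. Values were tested as log2(FPKM + 1), with a pseudocount of 1 and no further scaling, for the 10108 genes with a mean of at least 1 FPKM over the 6 libraries. The test was limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend), high minus low, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Gene lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, where at least 5 members were tested, and adjusted over the lists. The groups, the test, the alternatives, 42 gene lists and the rule for named genes were set before the data were examined. The rule names 12 fixed genes, of which Bach2, Bcl6, Irf4, Prdm1, Myc, Cd83, Cd86, Cxcr4, Ccr6, Cd38 and Il9r are given; some genes that the rule names are not reported here. It adds the 12 largest changes in each direction among genes past the threshold whose groups do not overlap (without immunoglobulin and T cell receptor segments, small RNA, predicted and ribosomal protein genes). It further names up to 4 members of each described list with the smallest p and up to 3 most abundant members of each quality or other cell list. Genes named as exceptions to a list or as members of a symbol family were chosen after their values were seen.

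The depth was estimated from genes under 0.15 FPKM, whose values in 1 library differ from those in another by a common ratio when both hold the same small number of fragments. Relative to low replicate 1, the depth was 0.81 and 0.9 in the other low libraries and 1.02, 1.03 and 1.21 in the high libraries. Given transcript lengths, this is about 10700000 to 15900000 fragments, an approximation that limits the precision of genes of a few FPKM. Pearson correlations of the log2 values across genes, which are not independent replicates, were 0.935 to 0.939 within the low group, 0.949 to 0.955 within the high group and 0.861 to 0.908 between groups, and principal component 1 held 53.7% of the variance. Any pair of libraries shared values within 1 percent in at most 6.8% of the genes, so no library was a copy of another.

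The limma step was tested on simulated data for this comparison, with the means and spread of the 10108 tested genes. It called 20 of 50 genes changed by a fold of 1.5, 36 of 50 at a fold of 2, 47 of 50 at 3 and 46 of 50 at 4, with 7 false calls among 9908 unchanged genes. Far fewer genes were changed here than the 56.5% called in the real comparison, and the noise of each gene was independent. These rates therefore need not hold for the real data. Camera called 10 of 10 shifted and 0 of 20 unchanged simulated lists, and with an estimated correlation it called 10 of the 10 shifted lists. The genes of all these lists were drawn independently of each other, so the counts do not show how camera treats genes that vary together.

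Other settings fixed in advance were pseudocounts of 0.1 and 5, no expression minimum or a mean of 5 FPKM, scaling to an equal total over the tested genes with or without immunoglobulin genes, upper quartile scaling, quantile normalization, eBayes without trend or robust, array weights, the replicate number as a block, symbols of every status kept, the highest row per symbol, and each library left out in turn. Removal of each library's trend with transcript length and GC content, and scaling without ribosomal protein and small RNA genes, were chosen after seeing the data. Lengths and GC content came from the longest GENCODE M21 transcript per symbol, matched by name only, for 98.8% of the tested genes.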

Results

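RNA was sequenced from germinal centre B cells of C57BL/6 mice that carry a Bach2-tdRFP reporter, in which a red fluorescent protein reads out the expression of Bach2, a transcriptional repressor of the B lineage. The cells came from the spleen, bound the hapten NP, a model antigen, carried IgG1 and belonged to the light zone, the part of the germinal centre where B cells meet antigen and helper T cells. They were sorted by flow cytometry into a tdRFP low and a tdRFP high group of 3 libraries each, and each library pooled cells of 3 mice. The comparison asked which transcripts differ between light zone cells with high and with low Bach2 expression. Expression is given in FPKM, as mean ± SD with n = 3 libraries per group. Log2 fold changes are high minus low on the log2(FPKM + 1) scale, which understates the change of low genes. The spacing of low values put the depth at about 13000000, 10700000 and 11800000 fragments in the low libraries. In the high libraries it was about 13400000, 13400000 and 15900000 fragments, and genes with a mean under 1 FPKM were not tested.

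The Bach2 transcript followed the sort. It measured 21.5, 14.4 and 9.13 FPKM in the low libraries and 47.9, 45.3 and 45.0 FPKM in the high libraries. The group means were 15.02 ± 6.23 and 46.1 ± 1.62 FPKM (log2 fold change 1.63, SE 0.26, limma adjusted p = 0.00233). The gene lies on chromosome 4, 32504410 to 32673083 in mm9. Bcl6, the repressor that maintains the germinal centre state, rose from 66.1 ± 9.36 to 124 ± 4.28 FPKM. Myc, the driver of growth in selected light zone cells, fell from 28.4 ± 2.66 to 14.98 ± 2.22 FPKM (log2 fold change −0.89, SE 0.13, limma adjusted p = 0.00141). The light zone surface molecules Cd83 (38.2 ± 10.5 to 176 ± 7.59 FPKM) and Cd86 (20.03 ± 5.99 to 121 ± 3.51 FPKM) rose. The dark zone chemokine receptor Cxcr4 fell from 105 ± 9.59 to 61.6 ± 4.27 FPKM. Irf4, a factor of plasma cell differentiation, measured 4.92 ± 2.05 and 3.86 ± 0.26 FPKM and did not pass (log2 fold change −0.22, limma adjusted p = 0.515). With the libraries scaled to equal totals its change was 0.05, and without low replicate 3 its fall passed (−0.54, limma adjusted p = 0.00989; range over the alternatives 0.00989 to 0.981). Prdm1, the plasma cell regulator, lay under the expression minimum. It measured 0.634, 1.19 and 0.352 FPKM in the low and 0.0563, 0.0420 and 0.0592 FPKM in the high libraries.

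**Figure D1:**
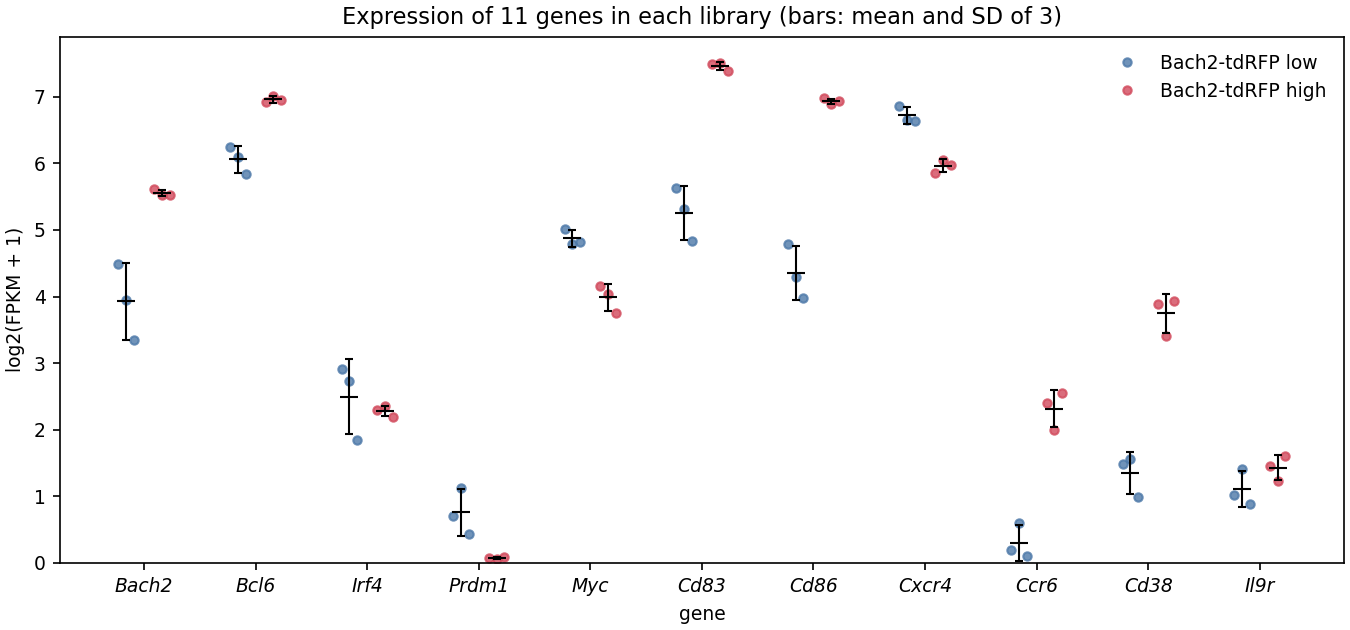
Expression of 11 genes fixed in advance, as log2(FPKM + 1) on the vertical axis, for each of the 3 Bach2-tdRFP low (blue) and 3 high (red) libraries; black bars are the mean and SD of each group. The 3 high libraries lie above every low library for Bach2, Bcl6, Cd83, Cd86, Ccr6 and Cd38 and below every low library for Myc, Cxcr4 and Prdm1, while the groups overlap for Irf4 and Il9r.

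Among all 10108 tested genes, 5713 (56.5%) differed between the groups, 2659 higher and 3054 lower in the high group. Of these, 1468 changed by at least 1 on the log2 scale, 745 upward and 723 downward. The groups did not overlap in 6727 tested genes (66.55%, against 10% by chance with 3 libraries in each group). The largest changes were ranked among genes past the threshold whose groups did not overlap. Immunoglobulin and T cell receptor segments, small RNA, predicted and ribosomal protein genes were left out. The largest rise in that ranking belonged to Il4i1, an amino acid oxidase induced by interleukin signals (5.45 ± 3.39 to 93.8 ± 10.5 FPKM, log2 fold change 4.06). It was followed by the actin-severing protein gelsolin, Gsn (13.2 ± 5.07 to 177 ± 5.55 FPKM), and the low affinity IgE receptor Fcer2a (34.0 ± 10.2 to 310 ± 11.3 FPKM). The complement receptor Cr2 rose from 8.34 ± 2.25 to 76.5 ± 6.32 FPKM. Crisp3, Cd72, Icosl, Cd36, Lta, Pld4, Aldoc and Hhex made up the rest of the 12 largest rises, with log2 fold changes of 3.17, 3.05, 2.99, 2.82, 2.79, 2.79, 2.75 and 2.62. The largest fall in that ranking belonged to the fatty acid binding protein Fabp5 (36.8 ± 12.9 to 2.29 ± 0.34 FPKM, log2 fold change −3.47). The glutathione transferase Gsto1 fell from 17.3 ± 3.36 to 1.44 ± 0.90 FPKM. The methyltransferase Smyd2 (14.5 ± 2.91 to 1.24 ± 0.08 FPKM) and the pyrophosphatase Ppa1 (66.2 ± 9.13 to 9.09 ± 1.61 FPKM) came next. The remaining 8 were Rangrf, BC048355, Gstt1, Asns, Lmo7, Bcat1, Fam46c and Shmt1, at −2.73, −2.66, −2.54, −2.52, −2.47, −2.38, −2.30 and −2.29. All 24 had a limma adjusted p of at most 0.00143 and groups that did not overlap. The direction split depended on the scaling. Summed FPKM was 641521, 684218 and 762285 in the low and 537903, 584744 and 545023 in the high libraries. With every library scaled to an equal total, 3820 genes were higher and 1761 lower (31.6% lower, against 53.5%), and the median of all genes moved from 0.01 to 0.30 on the log2 scale. Leaving ribosomal protein and small RNA genes out of that total gave 3521 higher and 2165 lower (38.1% lower).

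Genes that mark light zone B cells were higher in the high group. Of 16 tested light zone markers 14 rose (14 adjusted over the list alone) and 0 fell. Their median log2 fold change was 0.98 (camera adjusted p = 2.29e-06; adjusted p = 0.403 with an estimated correlation). Besides Fcer2a, Cd83 and Cd86, the transcription cofactor Lmo2 rose from 41.3 ± 5.68 to 167 ± 9.88 FPKM. The exceptions were Egr1, at 16.1 ± 7.10 and 17.6 ± 0.45 FPKM, and Cd69, at 18.0 ± 5.46 and 18.2 ± 0.96 FPKM. These and further exceptions to a list were named after their values were seen. Targets of CD40 and NF-kB rose in 15 of 19 tested members (16 adjusted over the list alone) and fell in 0. The list had a median of 0.88 (camera adjusted p = 7.62e-06; adjusted p = 0.483 with an estimated correlation). Among them Cd40 itself rose from 28.4 ± 2.37 to 54.9 ± 3.01 FPKM and the inhibitor Nfkbie from 9.76 ± 2.08 to 22.1 ± 1.73 FPKM. The survival gene Bcl2a1b rose from 59.7 ± 3.73 to 143 ± 12.3 FPKM, though Bcl2a1 copies share most of their sequence and their reads are uncertain. In the list of T cell help and cytokine receptors 13 of 18 tested members rose and 1 fell (13 and 1 adjusted over the list alone). The gene that fell was the signalling receptor Slamf6 (24.2 ± 1.42 to 18.4 ± 0.71 FPKM), a call lost with equal totals (limma adjusted p = 0.599; range over the alternatives 0.00262 to 0.599). This list had a median of 0.95 (camera adjusted p = 0.000427; adjusted p = 0.503 with an estimated correlation). The interleukin 4 receptor chain Il4ra rose from 11.98 ± 1.90 to 47.5 ± 1.40 FPKM and the common gamma chain Il2rg from 45.7 ± 7.84 to 110 ± 2.92 FPKM. Slamf1 rose from 14.2 ± 3.30 to 57.0 ± 0.67 FPKM, while Il9r measured 1.19 ± 0.43 and 1.70 ± 0.34 FPKM and did not pass.

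Genes of antigen presentation and of the B cell receptor were higher in the high group with few exceptions. In antigen presentation 16 of 17 tested members rose (16 adjusted over the list alone), and B2m, at 814 ± 159 and 1025 ± 93.4 FPKM, did not pass. B2m passed with equal totals (limma adjusted p = 0.00782), after quantile normalization (0.00589) and with the length and GC trend removed (0.00216). It also passed with ribosomal protein and small RNA genes left out of the totals (limma adjusted p = 0.0162) and without low replicate 2 (0.0475). Its limma adjusted p ranged from 0.00216 to 0.281 over the alternatives. The median was 1.34 (camera adjusted p = 1.76e-08; adjusted p = 0.403 with an estimated correlation). The class II chain H2-Ab1 rose from 1107 ± 80.2 to 2686 ± 150 FPKM. The peptide-loading regulators H2-Oa (44.0 ± 5.50 to 159 ± 6.06 FPKM) and H2-DMb1 (95.5 ± 16.6 to 267 ± 3.40 FPKM) rose with it. Of the 20 components of B cell receptor signalling 18 rose (18 adjusted over the list alone) and 0 fell. Their median was 1.13 (camera adjusted p = 1.76e-08; adjusted p = 0.466 with an estimated correlation). The adaptor Bank1 rose from 17.8 ± 4.25 to 95.3 ± 4.56 FPKM and the kinase Prkcb from 19.6 ± 2.83 to 54.8 ± 1.70 FPKM. The receptor chain Cd79b rose from 537 ± 36.5 to 1241 ± 40.8 FPKM and the inhibitory receptor Fcgr2b from 59.1 ± 3.02 to 130 ± 11.2 FPKM. Immediate response genes of the receptor did not move as a list (camera adjusted p = 0.232). Of 11 tested members 6 rose and 2 fell, also when adjusted over the list alone. Their median of 0.33 was 0.64 with equal totals and 0.20 with the length and GC trend removed. Egr3 rose from 1.46 ± 1.20 to 7.42 ± 1.32 FPKM and Nab2 from 4.49 ± 1.20 to 9.66 ± 1.00 FPKM, while Nfil3 fell from 9.91 ± 1.56 to 4.68 ± 1.31 FPKM. Alongside these groups, the summed FPKM of 14 macrophage and monocyte markers was 15.6, 277 and 14.4 in the low and 90.6, 121 and 73.3 in the high libraries. It was thus higher in the high group except for low replicate 2. Without Lyz1 and Lyz2, which neutrophils express too, the sum was 9.49, 34.6 and 6.76 in the low and 27.8, 29.2 and 25.8 in the high libraries. Without that library these markers passed as a list (median 1.74, camera adjusted p = 0.00179; range over the alternatives 0.00179 to 0.837). The antigen presentation list kept its call in each of the 6 fits that left out 1 library.

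Genes of growth and biosynthesis were lower in the high group. Of 30 tested MYC targets and ribosome biogenesis genes 29 fell (29 adjusted over the list alone), and Ppan, at 32.8 ± 7.67 and 29.4 ± 2.52 FPKM, did not pass. The list had a median of −1.26 (camera adjusted p = 6.33e-12; adjusted p = 0.403 with an estimated correlation). The mitochondrial chaperonin Hspd1 fell from 286 ± 42.9 to 63.2 ± 2.38 FPKM and the pyrimidine synthesis enzyme Cad from 23.7 ± 1.88 to 8.20 ± 0.45 FPKM. The purine synthesis enzyme Gart fell from 76.5 ± 9.20 to 23.7 ± 2.04 FPKM and the nucleolar protein Nolc1 from 53.4 ± 0.88 to 19.6 ± 2.50 FPKM. In the list of mTORC1 and amino acid supply 10 of 15 tested members fell and 2 rose (10 and 2 adjusted over the list alone). The rises were the stress response gene Ddit4 and the glutamine transporter Slc1a5. The call of Slc1a5 was lost without any 1 library other than low replicate 1 (limma adjusted p from 0.0542 to 0.108, and from 0.0026 to 0.108 over all alternatives). This list had a median of −0.89 (camera adjusted p = 0.00388; adjusted p = 0.403 with an estimated correlation). Its falls included the serine pathway enzymes Phgdh (186 ± 26.1 to 49.2 ± 10.1 FPKM) and Psat1 (135 ± 13.6 to 47.0 ± 5.23 FPKM). Shmt2 fell from 131 ± 5.49 to 38.4 ± 5.38 FPKM and the asparagine synthetase Asns from 22.9 ± 2.50 to 3.17 ± 0.47 FPKM. Glycolysis genes fell in 11 of 15 tested members (12 adjusted over the list alone). They had a median of −0.96 (camera adjusted p = 3.6e-05; adjusted p = 0.403 with an estimated correlation). Among them were Pgam1 (208 ± 5.80 to 80.2 ± 7.26 FPKM) and Tpi1 (248 ± 24.4 to 87.6 ± 12.3 FPKM). All 20 tested genes of oxidative phosphorylation fell (20 adjusted over the list alone). Their median was −0.94 (camera adjusted p = 1.25e-07; adjusted p = 0.466 with an estimated correlation). It was −0.62 with equal totals, where 19 fell, and −0.58 after quantile normalization, where 18 fell. The ATP synthase subunits Atp5b (637 ± 57.9 to 289 ± 18.6 FPKM) and Atp5a1 (486 ± 32.0 to 247 ± 11.6 FPKM) were among them.

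Ribosomal proteins fell in 19 of 24 tested members (21 adjusted over the list alone). Their median was −0.62 (camera adjusted p = 3.6e-05; adjusted p = 0.503 with an estimated correlation). Rps2 fell from 3339 ± 545 to 1112 ± 93.0 FPKM and Rpl3 from 1791 ± 283 to 907 ± 47.1 FPKM. Ribosomal protein genes made up 30.2%, 32.9% and 36.3% of the summed FPKM in the low libraries and 27.1%, 28.1% and 27.6% in the high libraries. With libraries scaled to equal totals the median of the list was −0.30, with 19 members lower and 1 higher, and after quantile normalization it was −0.20, with 12 lower and 1 higher. Genes of the heme and oxidative stress response fell in 8 of 10 tested members (8 adjusted over the list alone). They had a median of −1.26 (camera adjusted p = 0.00089; adjusted p = 0.403 with an estimated correlation). With a pseudocount of 5 it was −0.78. Both subunits of the glutathione synthesis enzyme fell, Gclm from 14.2 ± 0.65 to 3.95 ± 0.80 FPKM and Gclc from 14.5 ± 1.014 to 5.42 ± 0.26 FPKM. The thioredoxin reductase Txnrd1 fell from 34.3 ± 1.30 to 13.7 ± 0.63 FPKM and the peroxiredoxin Prdx1 from 670 ± 134 to 225 ± 24.2 FPKM. Cholesterol synthesis did not move as a list (camera adjusted p = 0.209). Of 18 members 6 fell and 0 rose, also when adjusted over the list alone. With equal totals 4 fell and 6 rose, and the median turned from −0.11 to 0.20. Idi1 fell from 118 ± 10.5 to 51.3 ± 4.06 FPKM and Lss from 14.4 ± 0.72 to 7.69 ± 1.24 FPKM.

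Cell cycle genes were lower in the high group. All 23 tested genes of G2 and mitosis fell (23 adjusted over the list alone). Their median was −1.21 (camera adjusted p = 4.35e-09; adjusted p = 0.466 with an estimated correlation). The mitotic activator Cdc20 fell from 102 ± 7.85 to 24.0 ± 5.31 FPKM, the cyclin Ccnb2 from 142 ± 8.73 to 47.0 ± 7.96 FPKM and the kinesin Kif20a from 50.6 ± 5.90 to 17.7 ± 2.09 FPKM. In the S phase list 20 of 21 tested members fell (20 adjusted over the list alone), and E2f1 measured 16.5 ± 3.23 and 17.3 ± 1.27 FPKM. The list had a median of −0.89 (camera adjusted p = 3.78e-08; adjusted p = 0.403 with an estimated correlation). With equal totals the S phase median was −0.59, and 17 members fell. The flap endonuclease Fen1 fell from 104 ± 7.10 to 50.3 ± 1.84 FPKM. The helicase subunit Mcm2 fell from 114 ± 1.77 to 66.6 ± 1.55 FPKM. G1 cyclins and CDK inhibitors did not pass as a list (camera adjusted p = 0.238), with 5 of 12 lower and 1 higher, also when adjusted over the list alone. With equal totals 4 were lower and 2 higher, and the median turned from −0.03 to 0.24. Fry called this list (fry adjusted p = 0.00382). Because it joins cyclins with inhibitors of their kinases, a median near 0 says little. Cdk4 fell from 239 ± 17.2 to 120 ± 6.25 FPKM, Ccnd3 from 177 ± 21.8 to 80.5 ± 2.92 FPKM and Ccne1 from 26.0 ± 2.81 to 11.03 ± 1.11 FPKM. Of 10 dark zone markers 8 fell and 2, Foxo1 among them, rose (8 and 2 adjusted over the list alone). They had a median of −0.95 (camera adjusted p = 0.00664; adjusted p = 0.503 with an estimated correlation). The call of Foxo1 was lost without low replicate 2 or any 1 high library (limma adjusted p from 0.0536 to 0.0548, and from 0.000917 to 0.32 over all alternatives). Gcet2 fell from 116 ± 9.96 to 41.2 ± 3.19 FPKM and the mitotic gene Ccnb1 from 113 ± 12.5 to 32.5 ± 7.01 FPKM. Plk1 fell from 85.2 ± 8.13 to 25.1 ± 5.29 FPKM and Mki67 from 194 ± 5.42 to 97.8 ± 10.1 FPKM. Genes of class switching and somatic hypermutation fell in 14 of 21 tested members and rose in 3, Rev1 and Prkdc among them (14 and 3 adjusted over the list alone). Their median was −0.49 (camera adjusted p = 0.00855; adjusted p = 0.403 with an estimated correlation). With equal totals 9 of these members were lower and 4 higher, with a median of −0.20, and the median was −0.30 with ribosomal protein and small RNA genes left out of the totals. The abasic site enzyme Apex1 fell from 55.8 ± 6.40 to 19.3 ± 3.13 FPKM. The end joining genes Xrcc6 (41.1 ± 4.86 to 17.9 ± 1.23 FPKM) and Lig4 (12.9 ± 1.15 to 5.25 ± 0.14 FPKM) fell as well.

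Genes that mark memory B cells were higher in the high group in 9 of 16 tested members and lower in 1, S1pr1 (9 and 1 adjusted over the list alone). The list had a median of 0.77 (camera adjusted p = 0.00606; adjusted p = 0.503 with an estimated correlation). The memory median was 0.39 with a pseudocount of 5 and 1.52 among members with a mean of at least 5 FPKM. The chemokine receptor Ccr6 rose from 0.246 ± 0.240 to 4.05 ± 0.95 FPKM and Cd38 from 1.58 ± 0.53 to 12.6 ± 2.58 FPKM. The transcription factor Hhex rose from 0.860 ± 0.478 to 10.2 ± 1.65 FPKM and lymphotoxin beta, Ltb, from 151 ± 6.26 to 436 ± 16.8 FPKM. Quiescence associated genes rose in 7 of 12 tested members and fell in 0 (7 and 0 adjusted over the list alone). Their median was 0.70 (camera adjusted p = 0.0019; adjusted p = 0.503 with an estimated correlation). It was 0.41 without low replicate 3 and 0.38 with a pseudocount of 5. The antiproliferative genes Btg1 (32.7 ± 5.49 to 89.7 ± 4.55 FPKM) and Btg2 (16.98 ± 3.52 to 49.7 ± 1.11 FPKM) rose. The redox regulator Txnip rose from 16.6 ± 6.01 to 44.6 ± 0.87 FPKM. Of 9 tested antiapoptotic genes 8 rose (8 adjusted over the list alone). They had a median of 0.76 (camera adjusted p = 0.000632; adjusted p = 0.403 with an estimated correlation). Mcl1 rose from 64.8 ± 7.25 to 112 ± 1.40 FPKM and Xiap from 10.2 ± 0.69 to 18.0 ± 1.71 FPKM. Proapoptotic genes did not pass camera as a list (camera adjusted p = 0.238), with 4 of 11 higher and 2 lower, also when adjusted over the list alone. Fry called these genes as a list (fry adjusted p = 0.0336). With equal totals 5 were higher and 1 lower, and the median moved from 0.21 to 0.53. Bmf rose from 1.52 ± 0.51 to 13.6 ± 0.88 FPKM and Fas from 81.8 ± 6.77 to 153 ± 2.29 FPKM. Migration and homing receptors rose in 11 of 16 tested members and fell in 3, Cxcr4, Rgs13 and S1pr1 (11 and 5 adjusted over the list alone). The list had a median of 0.81, or 0.49 with a pseudocount of 5 (camera adjusted p = 0.0489; adjusted p = 0.503 with an estimated correlation). S1pr3 rose from 6.14 ± 0.97 to 30.5 ± 0.90 FPKM and Cxcr5 from 41.7 ± 4.65 to 130 ± 2.22 FPKM. The call of the migration list was lost without low replicate 1 (camera adjusted p = 0.106), without high replicate 3 (0.075) and with equal totals (0.142). Its camera adjusted p ranged from 0.0191 to 0.142 over the alternatives.

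Transcription factors of the B lineage rose in 13 of 17 tested members and fell in 2 (13 and 2 adjusted over the list alone). Their median was 0.44 (camera adjusted p = 0.00171; adjusted p = 0.503 with an estimated correlation). It was 0.76 with equal totals and 0.73 after quantile normalization. The falls were Pou2af1 (518 ± 31.1 to 315 ± 7.60 FPKM) and Tcf3 (70.9 ± 4.17 to 46.5 ± 4.06 FPKM). With equal totals Tcf3 did not pass (limma adjusted p = 0.0822; range over the alternatives 0.000287 to 0.0822). Foxp1 rose from 4.34 ± 0.84 to 11.3 ± 0.11 FPKM, Bcl11a from 24.6 ± 2.39 to 51.8 ± 0.92 FPKM and Ets1 from 66.7 ± 8.51 to 111 ± 4.99 FPKM. Genes of germinal centre identity went both ways, with 9 of 15 higher and 4 lower (9 and 4 adjusted over the list alone; camera adjusted p = 0.213). The median of 0.36 was 0.68 with equal totals. Efnb1 rose from 18.1 ± 2.30 to 37.8 ± 1.03 FPKM. The histone methyltransferase Ezh2 fell from 96.3 ± 2.29 to 50.6 ± 2.33 FPKM, as did Rgs13, Gcet2 and Pou2af1. The plasma cell program did not pass camera as a list (median −0.43, camera adjusted p = 0.0539), with 7 of 13 lower and 1, Txndc5, higher, also when adjusted over the list alone. Fry called this program (fry adjusted p = 0.00615). With equal totals 6 were lower and 3 higher, with a median of −0.13. The call of Txndc5 was lost without low replicate 2 or high replicate 2 or 3 (limma adjusted p from 0.0511 to 0.0597, and from 0.000373 to 0.0597 over all alternatives). The joining chain Igj fell from 649 ± 109 to 222 ± 20.7 FPKM and Xbp1 from 83.4 ± 5.72 to 48.4 ± 2.46 FPKM. The camera adjusted p of this program was 0.0423 without low replicate 3 and 0.0303 without high replicate 2, with a range of 0.00665 to 0.304 over the alternatives. Genes of the endoplasmic reticulum stress response did not pass camera either (camera adjusted p = 0.213), with 5 of 14 lower and 2 higher, also when adjusted over the list alone. Fry called this list too (fry adjusted p = 0.0066). With equal totals 3 were lower and 4 higher, and the median turned from −0.21 to 0.11. The chaperone Hsp90b1 fell from 174 ± 13.6 to 101 ± 1.78 FPKM and Manf from 69.8 ± 9.58 to 35.5 ± 2.17 FPKM.

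In the list of AP-1, BATF and small MAF partners 2 of 9 fell and 0 rose (2 and 0 adjusted over the list alone, camera adjusted p = 0.93), against 1 lower and 2 higher with equal totals. The falls were Batf (33.1 ± 2.92 to 13.2 ± 2.57 FPKM) and Nfe2l2 (19.4 ± 1.06 to 15.5 ± 0.26 FPKM). Nfe2l2 no longer passed with equal totals (limma adjusted p = 0.958) or without high replicate 1 (limma adjusted p = 0.0571; range over the alternatives 0.0023 to 0.958). Interferon response genes rose in 4 of 9 tested members and fell in 1 (4 and 1 adjusted over the list alone). The list did not pass (camera adjusted p = 0.145), but did without low replicate 2 (0.00796, in a range of 0.00796 to 0.326 over the alternatives). The gene that fell was Bst2, from 21.8 ± 0.13 to 11.8 ± 1.46 FPKM. Of 7 tested follicular and marginal zone B cell markers 3 rose, Fcer2a, Cr2 and S1pr3, and S1pr1 fell (3 and 1 adjusted over the list alone; camera adjusted p = 0.227). Their median of 0.26 turned to −0.10 with the length and GC trend removed. The mean was 0.82, and fry called the list (fry adjusted p = 0.0064). Fcer2a and Cr2 were among the 12 largest rises named above.

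**Figure D2:**
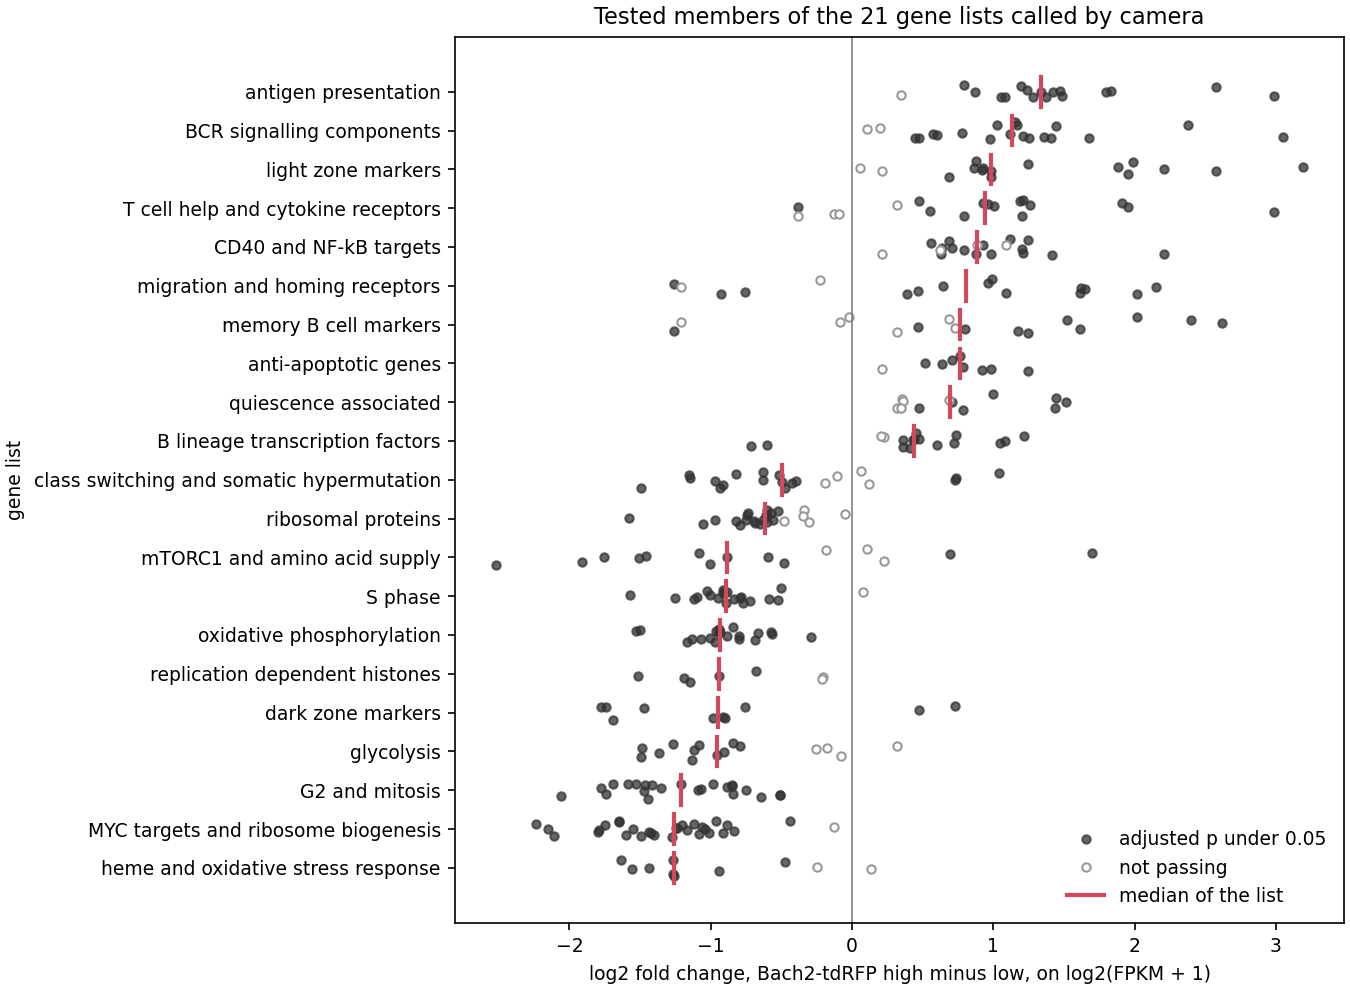
Log2 fold change (high minus low, on log2(FPKM + 1)) of the tested members of the 21 lists called by camera with a preset correlation, 1 line of points per list. Filled points have a limma adjusted p under 0.05, open points do not, and red bars are list medians, which run from −1.26 for the heme and oxidative stress response to 1.34 for antigen presentation.

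Camera with a preset correlation called 21 of the 35 lists with at least 5 tested members, 10 higher and 11 lower in the high group. With an estimated correlation camera called 0 lists, with adjusted p from 0.4 to 0.96 and 1 list at an unadjusted p under 0.05. Fry, which asks whether the members of a list move one way on balance without comparing them with other genes, called 27.

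Signs of sample quality and of other cells were measured in the same libraries. Heat shock and immediate early genes of tissue handling did not pass camera as a list (camera adjusted p = 0.327), with a median of 0.03 and a mean of −0.19. Fry called the list (fry adjusted p = 0.0329). Because it pools heat shock with immediate early genes, its median can hide opposite changes. The median was 0.35 with equal totals and −0.23 without low replicate 3. Of 14 members 5 fell and 1, Zfp36, rose (5 and 0 adjusted over the list alone). The falls included the heat shock genes Hsp90aa1 (969 ± 162 to 278 ± 5.07 FPKM), Hsp90ab1 (1502 ± 154 to 572 ± 36.1 FPKM) and Hspa8 (1593 ± 252 to 758 ± 33.6 FPKM). The call of Zfp36 was lost without low replicate 2 or any 1 high library (limma adjusted p from 0.0707 to 0.0985, and from 0.00255 to 0.0985 over all alternatives). Replication dependent histones fell in 5 of 7 tested members (5 adjusted over the list alone). Their median was −0.94 (camera adjusted p = 0.0489; adjusted p = 0.403 with an estimated correlation). The call of the histones was lost without low replicate 2 (camera adjusted p = 0.0649), low replicate 3 (0.0557), high replicate 2 (0.0544) or high replicate 3 (0.0547). Their range over the alternatives was 0.0119 to 0.187. Their median was −0.38 with a pseudocount of 5, −0.44 without an expression minimum and −0.57 with the length and GC trend removed. Of 4 tested sex linked genes the Y chromosome genes Ddx3y (14.5 ± 2.12 to 24.5 ± 1.46 FPKM), Kdm5d (4.10 ± 0.83 to 8.44 ± 0.24 FPKM) and Uty rose (3 adjusted over the list alone). Eif2s3y measured 65.5 ± 5.46 and 60.3 ± 3.22 FPKM.

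Neutrophil transcripts were abundant in low replicate 2, where S100a8 reached 497 FPKM and S100a9 456 FPKM, against at most 3.34 FPKM for either in the other 5 libraries. The same library held 3130 FPKM of Hba-a1 and 849 FPKM of Hbb-b1, against at most 79.8 and 86.6 FPKM elsewhere. Of the 6 tested neutrophil and 9 tested erythroid markers 0 passed limma (0 adjusted over the list alone, 1 at an unadjusted p under 0.05; camera adjusted p = 0.326 and 0.312 for the lists). Lyz2, a macrophage and neutrophil gene, measured 5.71, 215 and 6.43 FPKM in the low and 56.5, 79.4 and 42.1 FPKM in the high libraries. Without low replicate 2 Lyz2 passed (log2 fold change 3.05, limma adjusted p = 0.00136; range over the alternatives 0.00136 to 0.742). Of 5 tested macrophage markers Cd68 rose from 4.89 ± 1.44 to 11.2 ± 2.26 FPKM (1 adjusted over the list alone; camera adjusted p = 0.213 for the list). Of T cell markers Lck measured 23.7 ± 7.87 and 31.8 ± 2.69 FPKM and Cd8b1 1.58 ± 0.24 and 1.52 ± 0.29 FPKM, and 0 of 2 passed. Of 3 tested natural killer cell markers Il2rb fell (2.53 ± 0.78 to 1.09 ± 0.23 FPKM, limma adjusted p = 0.0167). Its call was lost without high replicate 2 (limma adjusted p = 0.0585) or high replicate 3 (limma adjusted p = 0.0502; range over the alternatives 0.00139 to 0.075). The tested dendritic cell marker Flt3 fell from 13.8 ± 0.65 to 10.7 ± 1.36 FPKM (limma adjusted p = 0.033). The call of Flt3 was lost in each of the fits without low replicate 1, 2 or 3 or high replicate 1 or 2 (limma adjusted p from 0.0511 to 0.108, and from 0.0163 to 0.774 over all alternatives). Of platelet and stromal markers 0 reached the expression minimum. With low replicate 2 left out, 5180 genes passed, 2442 higher and 2738 lower, and 86.5% of the 5713 genes kept their call and direction.

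**Figure D3:**
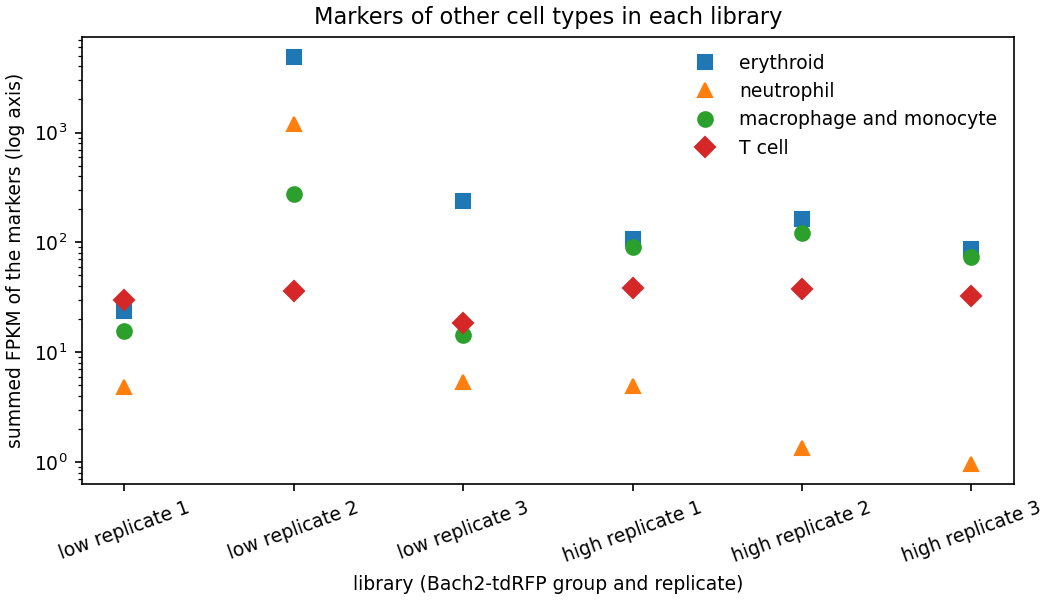
Summed FPKM of markers of 4 other cell types (log axis) in each of the 3 Bach2-tdRFP low and 3 high libraries. Low replicate 2 stands apart with 4862 FPKM of erythroid and 1186 FPKM of neutrophil markers, and T cell markers range from 18.4 to 38.5 FPKM.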

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

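The removal of the length and GC trend and the scaling without ribosomal protein and small RNA genes were chosen only after the results were seen, and all other alternatives were planned. The number of differing genes was 5713 and ranged from 4405 (without high replicate 1) to 6958 (array weights), and 0 genes called in both fits changed direction. Bach2 stayed higher, with log2 fold changes of 1.25 to 1.97. With libraries scaled to equal totals 1761 genes were lower, not 3054; leaving immunoglobulin genes out of the total gave the same 1761, since no immunoglobulin segment was among the tested genes. A change of at least 1 on the log2 scale as a further condition left 1468 genes. With an estimated correlation camera called 0 lists, with 1 at an unadjusted p under 0.05, and fry called 27. Of the 21 called lists 19 kept the call under every alternative that refits the genes; migration receptors kept it in 11 of 22 and replication dependent histones in 14 of 21. The plasma cell program was called in 4 of 22. Under 1 alternative each, camera called germinal centre identity (quantile normalization), interferon response and macrophage markers (both without low replicate 2) and erythroid markers (array weights). The depth limits the precision of genes of a few FPKM.

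Deviations from the group means gave no sign that the replicate numbers pair the libraries. Those of libraries with the same number correlated across genes with r of −0.006, −0.033 and −0.024, and no library correlated best with the one of its own number. Correlations so close to 0 cannot show whether such libraries came from the same mice, which the labels do not say. With the number as a replicate block 5321 genes passed, 2465 higher and 2856 lower, and the camera adjusted p of migration receptors was 0.053, in a range of 0.0191 to 0.142 over the alternatives.

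Among the genes named here, log2 fold changes that reversed belonged to genes that had not passed, and other genes were not examined for it one by one. Scaling to equal totals, with or without immunoglobulin genes, gave 0.048 for Irf4, 0.203 for Eif2s3y, 0.185 for Cd8b1 and 0.184 for Ppan. The scaling without ribosomal protein and small RNA genes gave 0.098 for Eif2s3y, 0.123 for Cd8b1 and 0.081 for Ppan. Upper quartile scaling gave 0.026 for Cd8b1 and quantile normalization 0.153 for Eif2s3y. Removal of the length and GC trend gave −0.043 for Cd69, 0.207 for Cd8b1, −0.14 for E2f1 and −0.143 for Egr1. Array weights gave −0.045 for Csf1r, −0.008 for E2f1, −1.093 for Lyz1, −1.006 for Lyz2 and −0.019 for Mpeg1. Over the fits without 1 library, log2 fold changes ranged from −0.241 to 0.048 for Ppan, from −4.297 to 1.505 for Hba-a1, from −2.123 to 0.846 for Hbb-b1 and from −0.128 to 0.032 for Cd8b1. They ranged from −0.153 to 0.268 for Cd69, from −0.081 to 0.184 for E2f1 and from −0.111 to 0.512 for Egr1. Low replicate 1 (Ppan), low replicate 2 (Hba-a1, Hbb-b1 and Cd8b1), low replicate 3 (Cd69, E2f1 and Egr1) and high replicate 2 (Cd8b1) were the libraries whose absence reversed the sign. For these genes and lists the cause was not tested.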

Other observations

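The symbol families, the removal of the length and GC trend, the scaling tests of single lists and the tests of dark zone, macrophage, neutrophil and erythroid transcripts were chosen only after the results were seen, and the fits without a library and the splits were planned. Of 18 symbol families tried, 4 that were lower in the high group are described first. Families of tRNA synthetases, mitochondrial import, translation initiation factors, nuclear RNA polymerases and the spliceosome were lower too, and TNF receptors higher. They passed camera at the preset correlation but not at an estimated one. Vacuolar ATPase genes did not pass, with 4 of 16 higher and 4 lower (camera adjusted p = 0.771). Septins and actin regulators did not pass either (camera adjusted p = 0.124). Mitochondrial ribosomal proteins fell in 72 of 76 tested members and rose in 0 (median log2 fold change −0.83, and 59 members and −0.53 with libraries scaled to equal totals), with Mrps10 falling from 40.5 ± 3.97 to 13.6 ± 0.41 FPKM (mean ± SD, n = 3 libraries). All 7 tested subunits with a Cct symbol, of the CCT chaperonin, which folds actin and tubulin, fell (median −1.32), such as Cct6a, from 214 ± 33.8 to 63.3 ± 4.06 FPKM. Proteasome subunits and assembly factors fell in 40 of 47 tested members, while 2 rose, the immunoproteasome subunits Psmb10 (75.4 ± 2.72 to 113 ± 1.497 FPKM) and Psmb9 (231 ± 10.5 to 282 ± 16.1 FPKM), and the median of −0.85 was −0.53 with equal totals, where 35 fell and 6 rose. Psmb9 did not pass without low replicate 2 or high replicate 2 or 3 (limma adjusted p from 0.0721 to 0.0777, and from 0.000318 to 0.0894 over all alternatives). Glutathione S-transferases fell in 7 of 8 tested members (median −1.33), with Gstt2 falling from 58.5 ± 10.1 to 12.7 ± 0.61 FPKM. These 4 families passed camera with adjusted p from 9.43e-16 to 0.000388 and had adjusted p = 0.24 with an estimated correlation; their medians kept their sign under every scaling.

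Families of receptors and antigen processing went the other way. Class I and class II histocompatibility genes rose in 23 of 25 tested members (median 1.14, camera adjusted p = 7.22e-10; adjusted p = 0.24 with an estimated correlation), with H2-D1 rising from 227 ± 41.7 to 429 ± 26.8 FPKM; class I copies are similar in sequence and their reads are uncertain. Cathepsins rose in 6 of 9 tested members (median 0.79, camera adjusted p = 0.00128; adjusted p = 0.24 with an estimated correlation), among them Ctsa, from 15.9 ± 3.01 to 50.4 ± 2.56 FPKM. All 4 tested toll-like receptors rose, with Tlr1 at 8.35 ± 0.97 and 35.5 ± 2.15 FPKM and Tlr9 at 11.02 ± 1.79 and 32.2 ± 0.57 FPKM. Macrophages express cathepsins and toll-like receptors too, and the summed macrophage markers were at 73.3 to 121 FPKM in the high libraries, against 15.6, 277 and 14.4 FPKM in the low libraries. Of 4 tested TNF and lymphotoxin ligands Lta, Ltb and Tnf rose and Tnfsf9, at 6.56 ± 1.48 and 7.54 ± 1.17 FPKM, did not pass. Tnf rose from 7.19 ± 3.67 to 33.6 ± 1.16 FPKM. Interleukin receptors rose in 8 of 15 tested members and fell in 1, Il2rb, which did not pass with libraries scaled to equal totals or without high replicate 2 or 3 (median 0.73, and 0.39 with the length and GC trend removed; camera adjusted p = 0.00215; adjusted p = 0.3 with an estimated correlation). Il10ra rose from 1.39 ± 0.60 to 13.1 ± 0.34 FPKM and Il5ra from 0.712 ± 0.394 to 6.95 ± 0.46 FPKM. Zinc finger genes named Zfp rose in 76 and fell in 14 of 229 tested members (median 0.23, camera adjusted p = 9.3e-05; adjusted p = 0.28 with an estimated correlation). Equal totals gave 117 higher, 3 lower and a median of 0.52, quantile normalization gave 57, 22 and 0.08, and removal of the length and GC trend gave 75, 21 and 0.24.

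Growth and cell cycle genes were lower in the high group, as were short transcripts (median −0.39 in the shortest of 10 classes and 0.24 in the longest), but with each library's length and GC trend removed, the medians stayed at −1.34 for MYC targets, −1.22 for G2 and mitosis and −0.69 for oxidative phosphorylation, which argues against that trend as their whole cause, while ribosomal proteins moved from −0.62 to −0.35, which left the size of their fall open. Equal totals gave −0.98 for MYC targets, which argues against the scaling as the whole cause there, and −0.30 for ribosomal proteins, whose fall the scaling may account for in part. A larger share of dark zone cells in the low sort, which the light zone gate should remove, is a candidate explanation that cannot be told apart from a change within light zone cells: of 6 dark zone markers outside the cell cycle 4 fell (Cxcr4, Polh, Gcet2 and Cd24a), but Foxo1 rose (log2 fold change 0.48, and 0.12 with the length and GC trend removed). Without low replicate 2 or any 1 high library the fold change of Foxo1 stayed at 0.41 to 0.48, although its limma adjusted p lay at 0.0536 to 0.0548, in a range of 0.000917 to 0.32 over the alternatives. A difference of light zone cells with their Bach2 level, which the sort names, also stays open and was not tested apart from these.

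Antigen presentation genes were higher in the high group. Removal of the length and GC trend left their median at 1.45, which argues against that trend. RNA of macrophages or monocytes, which the sort should remove, could raise class II transcripts: their marker sum was 73.3 to 121 FPKM in the high libraries against 15.6 and 14.4 in 2 low libraries, but it reached 277 in low replicate 2. Neutrophils, whose transcripts that library held, express Lyz1 and Lyz2 too, and without these genes the sum was 34.6 FPKM there, against 25.8 to 29.2 FPKM in the high libraries, while the antigen presentation sum was 8703 against at least 19860 FPKM. That single library excludes nothing by itself, and such RNA cannot be told apart from a change in B cells as a part of the rise, since of the 5 tested markers Cd68 rose and Lyz1, Lyz2 (the most abundant), Csf1r and Mpeg1 passed without low replicate 2, with log2 fold changes of 2.28, 3.05, 1.74 and 1.47.

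Low replicate 2 held neutrophil and erythroid transcripts. All 17 of the neutrophil and erythroid markers in the tables were highest in that library, in line with RNA of neutrophils and erythroid cells there, and the neutrophil sum was 1186 FPKM against at most 5.34 FPKM elsewhere. Without that library 86.5% of the differing genes kept their call and direction, against 76.5% to 93% without each of the other libraries. A gene that differs only through 1 library has a wide spread within its group and is seldom called. The share therefore cannot decide how far that library is a source of the differences between the groups.

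Of the 10 splits of the 6 libraries into 3 and 3, the real split gave 5713 differing genes and the highest of the others gave 4, and 1 split, the real one, gave as many. With 10 splits the share cannot fall under 0.05. Every other split mixes low and high libraries on each side. The group difference then widens the spread within each side, so few calls are bound to follow. The counts of those splits therefore do not measure how many calls chance would give.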
